A study of Mus musculus with 6 samples.

How the data were processed

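RNA-seq libraries of 3T3-L1 cells, a mouse fibroblast line that can be turned into fat cells, were analysed from 2 groups of 3 libraries. Per the labels, preadipocytes were induced with 0.5 mM isobutylmethylxanthine, 1 µM dexamethasone and 1 µg/ml insulin in medium with 10% serum. Mature adipocytes taken 8 days after induction were then kept for 5 further days, either alone or in a transwell dish that shared its medium with Panc-1 cells, an established human pancreatic cancer line. The membrane keeps the cell types apart, and per the labels RNA was extracted from the mature adipocytes. The share of cells left undifferentiated was not measured. Replicate numbers came from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

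Each library was deposited as a table of filtered variant calls, positions at which the RNA reads differed from the mouse reference genome, and no table of reads per gene was used here. Per the submitters' processing notes, Bowtie2 and the build mm10 were used, and neither versions nor settings are named there. The variant caller is not given in the sources used here. Per the file headers, each position was annotated with its gene, its region of the gene, its cytogenetic band, segmental duplications and dbSNP. The deposited values used were the counts of reads at each called position, split in the genotype field into reads with the reference base and reads with the alternate base, and the caller's quality score. The deposited score served only for 1 alternative, in which calls above each library's median score were kept. Each file names filter words beside its calls, and calls with such a word were kept. A word for clustered calls marked 18.29 to 19.57% of the calls per library. Passing calls alone were an alternative for the number of calls and the A-to-G share only. Depth per gene, lists and allele fractions were not measured from passing calls alone. Positions on the chromosomes X, Y and M carried no gene, dbSNP or duplication annotation in the files (15703 calls on X, 1931 on Y and 6 on M over the libraries). X-linked genes are therefore absent from the per-gene depth and were measured separately.

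Coordinates are those of mm10, counted from 1. Gene strands, exons and coding sequences were taken from GENCODE for the same assembly, and the reference base of all 63091 substitutions inside GENCODE exons equalled the annotation's base. Coding effects were computed here, because the files list the effect of each exonic call as unknown. Protein changes name the reference residue, its number from the first methionine of the principal transcript, and the changed residue.

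A count model needs a count per gene, and the read depth at positions where 3T3-L1 cells differ from the reference supplied it. For each gene the depth was summed over exonic and untranslated positions called in all 6 libraries and lying at least 200 bases apart, starting from the deepest position. This gave 6471 genes from 26470 positions. After filterByExpr, 6265 genes were tested by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the F statistic. Genes without a shared exonic variant, or too weakly expressed to be called in every library, could not be measured. The depth is a count of reads at a few bases of a gene, so PCR duplicates and local coverage enter it, and the deposited counts carry no strand.

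The deposited read counts reach at most 920 to 938 at any position, and the libraries converge at deep positions: coculture replicate 2 had a median of 0.337 of the depth of alone replicate 3 at positions with a mean of 50 to 100 reads and 0.712 at positions above 600. Fold changes of genes read at deep positions are therefore compressed, and those involving this shallow library are shifted upwards in coculture. A fit restricted to positions with a mean depth up to 150 was added after seeing the data.

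The 20 gene lists and the tests of the comparisons were fixed before the data were examined. Tests and settings chosen later are named as such where they appear. Lists with at least 3 measured members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), which compares the members with all other measured genes. The lists were adipocyte identity, fatty acid and triglyceride synthesis, lipolysis and fatty acid oxidation, cholesterol synthesis, inflammation and acute phase, interferon response, extracellular matrix and myofibroblast, preadipocyte, glycolysis and hypoxia, oxidative phosphorylation, endoplasmic reticulum stress, cell cycle, lysosome and autophagy, thermogenic adipocyte, Wnt and TGF-beta signalling, antioxidant response, RNA editing enzymes, and markers of immune, epithelial, and endothelial or muscle cells. Genes were named by rule: the 6 highest and 6 lowest fold changes among called genes with a mean depth of at least 30 and no overlap between groups, up to 3 members per list with the smallest p, and a few adipocyte genes whatever their result. Gene models of uncertain mapping were counted and not named under the first part of the rule. List members named beyond these 3, called or not, were chosen after their values were seen.

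Substitutions were read on the transcribed strand where genes of only 1 strand cover the position (79.2% of 595737 distinct substitutions). The share of A-to-G substitutions, which is where A-to-I RNA editing appears, was compared between groups by a two-sided exact permutation test, as were other values per library. With 3 libraries against 3 this test cannot give a p below 0.1. Allele fractions were tested at substitution positions called in all 6 libraries, with a depth of at least 10 in each and some reference reads. The test was an edgeR model of alternate and reference counts with a term per library. Positions called in only 1 group, such as Blcap Q5R and Y2C, could not enter it. Shares in single libraries carry 95% Wilson intervals, which cover counting error only.

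Within groups, pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 1.70 to 3.91 over genes), so none is a copy of another; this does not show whether they were separate cultures. The fits were tested on simulated data. For depth per gene in the 6246 simulated genes, 51% of 1.5-fold and 92% of 2-fold changes were recovered, with 11 unchanged genes called. For allele fractions at 25543 simulated positions, 61% of changes by 0.2 and 89% of changes by 0.3 were recovered, with 2 unchanged positions called. The simulated allele reads varied by counting error only, with no further spread between the libraries of a group. Where real libraries vary more, recovery may be lower and false calls more frequent. Other settings fixed in advance covered DESeq2 1.42.0 (its size factors and its test), limma-voom, the low-count filter, a replicate block, the choice of positions, depth minimums, other list tests and leaving out each library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 were used for the rest.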

Results

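RNA sequencing was used to ask how mature 3T3-L1 adipocytes change when they share medium with pancreatic cancer cells. Adipocytes 8 days after induction were cultured for 5 further days alone (n = 3 libraries) or in indirect coculture with Panc-1 cells (n = 3 libraries). The calls in each library list the positions at which its reads differed from the mouse genome, with the number of reads behind each. There were 349562, 383482 and 396431 calls in the libraries cultured alone, and 361508, 204104 and 355101 in coculture. The reads at called positions summed to 8203008, 9263265 and 9705943 in alone and to 8683269, 3661917 and 8688204 in coculture, so coculture replicate 2 was the shallowest library. Most calls lay in introns (57.4 to 65.4% per library), and 72.1 to 74.2% were homozygous. Between 87.3 and 88.1% of the calls in each library are listed in dbSNP.

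The mean number of calls was 376492 ± 24200 in alone and 306904 ± 89090 in coculture (SD, n = 3 each), a difference smaller than the spread between the coculture libraries (exact permutation test, two-sided p = 0.3; the smallest possible is 0.1). Depth per position did not scale evenly across libraries. Coculture replicate 2 held 0.32 of the depth of alone replicate 3 at positions with a mean of 20 to 50 reads, and 0.712 at positions above 600. For strongly expressed genes the coculture mean is therefore raised by this library, and fold changes at deep positions are compressed.

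**Figure D1:**
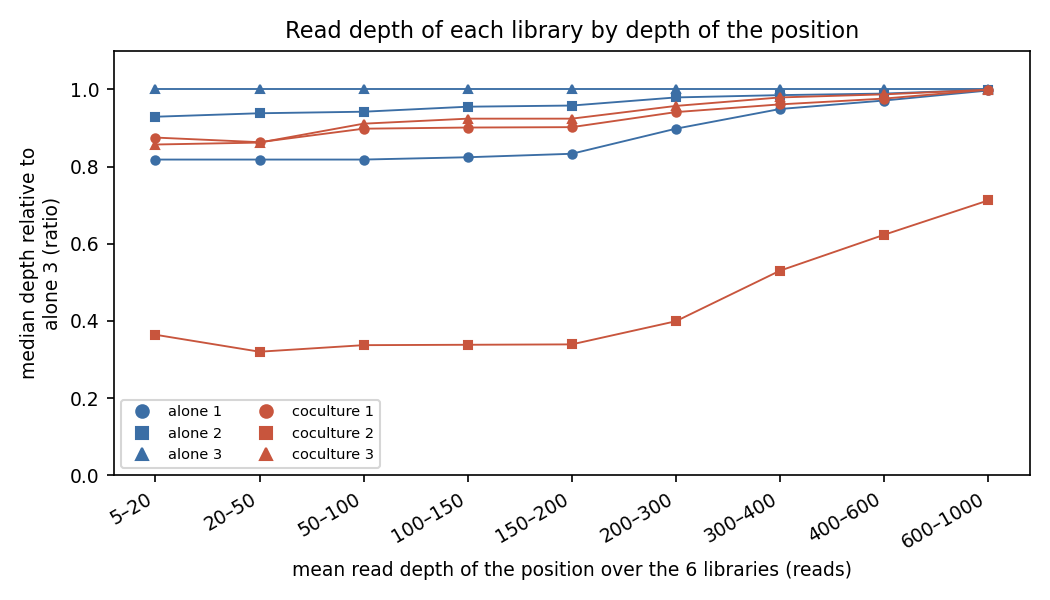
Median read depth of each library relative to alone replicate 3 (vertical axis, ratio) for positions called in all 6 libraries, grouped by their mean depth in reads (horizontal axis). The ratio of coculture replicate 2 stays between 0.32 and 0.364 up to a mean of 200 reads and rises to 0.712 in the deepest group.

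Among called genes with a mean depth of at least 30 reads, Eno2, Adm and Fosl1 rose most in coculture, and Pitpnm2os1, Prlr and Nos3 fell most. Eno2, a glycolytic enolase, had a log2 fold change of 3.31 ± 0.45 (SE) and reached 34.8 ± 18.2 TMM-normalised CPM (the depth as counts scaled to library size) in coculture from 3.11 ± 0.60 in alone (SD, n = 3 each). Adm, which encodes the vasodilator adrenomedullin, rose by 2.79 ± 0.24, and Socs3, a feedback inhibitor of cytokine receptors, rose 5.66-fold (2.50 ± 0.09) from 24.5 ± 0.94 to 138 ± 6.48 CPM. The AP-1 gene Fosl1 (2.58 ± 0.14), Rtn4rl2 (2.47 ± 0.22), which encodes a receptor related to the Nogo receptor, and the AMP deaminase gene Ampd3 (2.38 ± 0.20) complete the 6 largest rises at that depth. Lep, which encodes leptin, fell 4.02-fold (-2.01 ± 0.19), from 17.3 ± 0.71 to 4.41 ± 0.77 CPM. Nos3, the endothelial nitric oxide synthase gene, fell from 306 ± 20.1 to 66.9 ± 4.91 (-2.19 ± 0.09), and the prolactin receptor gene Prlr fell by 2.28 ± 0.15 on the log2 scale. Mfng, a glycosyltransferase of the Notch pathway, had a log2 fold change of -1.90 ± 0.22. The noncoding transcripts Pitpnm2os1 (-3.12 ± 0.28) and Ctcflos (-1.99 ± 0.10) complete the falls, and because the reads carry no strand those of Pitpnm2os1, which lies within Pitpnm2, cannot be assigned with certainty.

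These 12 genes were past the threshold with adjusted p-values from 8.45e-06 (Socs3) to 0.00141 (Eno2) in edgeR's quasi-likelihood test, and no coculture library overlapped an alone library. Eno2 (mm10, chromosome 6, 124760053 to 124769673), Adm (chromosome 7, 110627661 to 110629820), Fosl1 (chromosome 19, 5447547 to 5455946) and Rtn4rl2 (chromosome 2, 84871924 to 84886710) were each read at 1 position. The position in Fosl1 also lies within Ccdc85b, which itself rose (1.58 ± 0.11 on the log2 scale), so those reads can belong to either gene. At least 1 measured position of Ampd3 also lies within Rnf141, of Adm within Gm28863, of Nos3 within Gm15587 and of Prlr within Gm21973. Socs3 (chromosome 11, 117966079 to 117970047) and Lep (chromosome 6, 29060220 to 29073877) were read at 2 positions and Nos3 (chromosome 5, 24364810 to 24384474) at 10. Of the genes to be reported whatever their result, Pparg (-0.28 ± 0.26), Fabp4 (0.83 ± 0.47), Ccl2 (-0.31 ± 0.28) and Col1a1 (0.25 ± 0.12) were not past the threshold. Pparg, Fabp4 and Ccl2 were each read at only 1 position, with mean depths of 32.8, 22.8 and 29.2 reads. Their values do not show that these genes were unchanged. Adipoq, Saa3, Il6, Wnt5a and Adar had no exonic position called in all 6 libraries and were not measured.

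**Figure D2:**
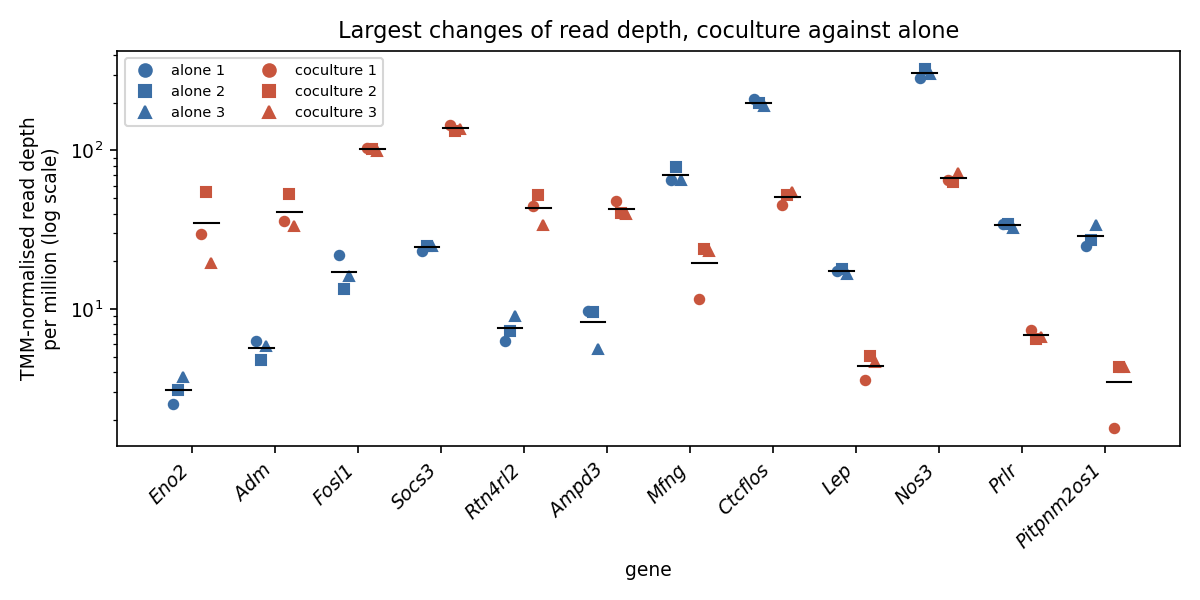
TMM-normalised read depth in CPM (vertical axis, log scale) of the 6 called genes with the largest and the 6 with the lowest log2 fold change at a mean depth of at least 30 reads, uncertain gene models aside, from Eno2 (3.31) to Pitpnm2os1 (-3.12). Each point is a library, bars are group means (n = 3), and for each gene all coculture libraries lie on the same side of the libraries cultured alone.

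Over all genes, 817 were higher and 808 lower in coculture among 6265 tested (25.9%), of which 149 were at least 2-fold higher and 100 at least 2-fold lower. The groups did not overlap for 2808 genes (44.8%, against 10% by chance). At an unadjusted p under 0.05 there were 2362 genes. The counts of higher and lower genes were 1066 and 1100 without coculture replicate 2. The higher count dropped to 529 without alone replicate 1 and 500 without alone replicate 2, and to 531 with 1 position per gene or 502 at homozygous positions. The lower count dropped to 455 without alone replicate 2, 508 without alone replicate 3, 519 without coculture replicate 1 and 501 at homozygous positions.

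Of 18 measured inflammation and acute phase genes, 8 rose and none fell (9 rose when adjusted over the list alone). Besides Socs3, Serpina3n, which encodes a serine protease inhibitor of the acute phase, rose 4.81-fold (2.27 ± 0.17, SE), and Nfkbiz, a nuclear regulator of NF-kB target genes, rose 1.80-fold (0.85 ± 0.08). The interleukin 1 receptor gene Il1r1 (0.87 ± 0.09), Csf1 (0.88 ± 0.21), Il6st, the shared receptor chain of the interleukin 6 family (0.52 ± 0.12), Steap4 (0.39 ± 0.09) and Nfkb2 (0.29 ± 0.08) also rose. The list's camera adjusted p was 0.0019, against adjusted p = 0.30 with an estimated correlation. Chemokine Ccl2 (-0.31 ± 0.28) was among the 10 members not past the threshold, and Cd14, the only measured immune cell marker, rose as well (1.58 ± 0.16).

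Interferon response genes moved the other way, with 6 of 13 measured members lower and none higher (8 lower when adjusted over the list alone). Usp18, which removes the ubiquitin-like ISG15 from proteins, fell 3.39-fold (-1.76 ± 0.18), and the guanylate-binding protein gene Gbp3 fell 3.09-fold (-1.63 ± 0.21). The immunoproteasome genes Psmb9 (-0.89 ± 0.17) and Psmb8 (-0.95 ± 0.21), the peptide transporter gene Tap1 (-0.49 ± 0.10) and Gbp2 (-0.48 ± 0.10) fell as well. The camera adjusted p was 0.0019, against adjusted p = 0.44 with an estimated correlation. Irf9 (-0.40 ± 0.15) and Eif2ak2 (-0.30 ± 0.11) were not past the threshold.

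Extracellular matrix and myofibroblast genes were higher, with 7 of 24 measured members past the threshold and none lower (7 when adjusted over the list alone). The fibril-associated collagen gene Col12a1 rose 3.76-fold (1.91 ± 0.11), the matricellular gene Cyr61 2.95-fold (1.56 ± 0.21) and Lox, which encodes a collagen cross-linking oxidase, 1.82-fold (0.86 ± 0.17). Serpine1 (0.99 ± 0.19), Acta2, the smooth muscle actin gene (0.74 ± 0.16), Timp3 (0.72 ± 0.17) and Thbs2 (0.36 ± 0.10) rose too. The list's adjusted p was 0.0019, and adjusted p = 0.44 with an estimated correlation. It was 0.0039 without coculture replicate 2, 0.047 at positions of mean depth up to 150, and 0.089 with both changes together. Below that depth Col12a1 had 1.90 ± 0.11 and Lox 1.57 ± 0.31.

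Glycolysis and hypoxia genes were higher in 4 of 11 measured members (4 when adjusted over the list alone), with an adjusted p of 0.016 and adjusted p = 0.44 with an estimated correlation. Beside Adm these were Hk1, a hexokinase gene (0.90 ± 0.09), P4ha2, which encodes a collagen prolyl hydroxylase subunit (0.60 ± 0.17), and Ndrg1 (0.89 ± 0.26); P4ha2 lost its call without alone replicate 1 (adjusted p = 0.102), 2 (0.108) or 3 (0.101). Vegfa (0.52 ± 0.33) and Hk2 (0.36 ± 0.19) were not past the threshold. Of 6 measured preadipocyte genes, the surface marker genes Thy1 (1.21 ± 0.09) and Cd44 (1.24 ± 0.27) rose and Zfp423, an adipogenic commitment factor (-0.77 ± 0.16), fell. That list was not past the threshold (adjusted p = 0.16, 2 higher and 1 lower when adjusted over the list alone), and Cd44 lost its call without alone replicate 2 (0.053) or coculture replicate 3 (0.0522). Tgfbr2 (0.82 ± 0.09) and Lef1 (0.55 ± 0.12) rose among 6 Wnt and TGF-beta genes, where Tcf7l2 (0.27 ± 0.13) was not past the threshold (list adjusted p = 0.16, 2 when adjusted over the list alone). The replication licensing genes Mcm2 (0.78 ± 0.10), Mcm6 (0.51 ± 0.10) and Mcm3 (0.28 ± 0.08) rose among 14 cell cycle genes (list adjusted p = 0.16, 3 when adjusted over the list alone), and Mcm3 lost its call without any 1 library other than coculture replicate 2 (adjusted p from 0.0609 to 0.135).

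Genes of fat breakdown were lower in part: 5 of 10 measured lipolysis and fatty acid oxidation genes fell and none rose (5 when adjusted over the list alone). Mgll, the monoacylglycerol lipase gene, fell 2.75-fold (-1.46 ± 0.16), Ppargc1a, a coactivator of mitochondrial genes, had -0.98 ± 0.11, and Cpt1a, which encodes the carnitine transferase of long-chain fatty acid import, had -0.53 ± 0.10. Slc25a20 (-0.83 ± 0.16) and Ppara (-0.79 ± 0.17) fell as well. The fatty acid oxidation enzyme genes Decr1, Hadh, Acadm, Acadl and Eci1 were not past the threshold, and the list members Pnpla2 and Lipe were not measured. The list's adjusted p was 0.023, and adjusted p = 0.44 with an estimated correlation. It was 0.054 without alone replicate 1, 0.072 without coculture replicate 1 and 0.076 without coculture replicate 3. The coactivator genes Ppargc1a and Ppargc1b (-0.54 ± 0.14) were the members lower among 4 measured thermogenic genes (list adjusted p = 0.13, 2 when adjusted over the list alone), and Pdk4 (-0.26 ± 0.19) was not past the threshold. Ppargc1b lost its call without any 1 of the alone libraries or coculture replicate 1 (adjusted p from 0.0612 to 0.0994).

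Cholesterol synthesis genes were lower in 5 of 14 measured members (6 when adjusted over the list alone). Tm7sf2 (-1.30 ± 0.12) and Dhcr24 (-1.12 ± 0.10), which encode sterol reductases late in the pathway, fell most, followed by Mvk (-0.38 ± 0.12), Idi1 (-0.37 ± 0.08) and Dhcr7 (-0.30 ± 0.08). Hmgcr, the gene of the rate-limiting reductase, had -0.13 ± 0.10 and was not past the threshold. The list had an adjusted p of 0.023, and adjusted p = 0.44 with an estimated correlation. It was 0.054 without alone replicate 1, where Idi1 also lost its call (0.0611), and 0.063 without coculture replicate 1.

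The adipocyte identity list was not past the threshold. Of 21 measured members, 5 fell (Lep, Car3, Apoe, Klf15 and Irs1) and none rose (6 fell when adjusted over the list alone). Car3, an abundant adipocyte carbonic anhydrase gene, fell 2.15-fold (-1.10 ± 0.09) and Apoe 1.66-fold (-0.73 ± 0.09), while the fatty acid transporter gene Cd36 (0.70 ± 0.32) and the lipase gene Lpl (0.68 ± 0.34) were not past the threshold. The list median was 0.22, its mean was -0.04 and camera placed it lower with an adjusted p of 0.33. That adjusted p was 0.056 without coculture replicate 2, 0.23 at positions of mean depth up to 150, and 0.25 with both changes together. The fatty acid and triglyceride synthesis genes Acacb (-0.76 ± 0.09), Srebf1 (-0.75 ± 0.13) and Dgat1 (-0.56 ± 0.15) fell among 13 measured members (3 when adjusted over the list alone), though Dgat1 lost its call without alone replicate 1 (adjusted p = 0.0656), alone replicate 2 (0.0828) or coculture replicate 1 (0.0567). That list had a median of 0.15, a mean of 0.10 and a lower camera direction with an adjusted p of 0.66, or 0.019 at positions of mean depth up to 150. With an estimated correlation its camera adjusted p was 0.81. The respiratory chain genes Ndufv1 (-0.68 ± 0.09), Cox5b (-0.81 ± 0.13) and Ndufa9 (-0.60 ± 0.12) fell among 13 oxidative phosphorylation genes (6 when adjusted over the list alone), with a list adjusted p of 0.13, or 0.019 at positions of mean depth up to 150 and 0.018 without coculture replicate 2. Camera with an estimated correlation gave the oxidative phosphorylation list an adjusted p of 0.53.

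Endoplasmic reticulum stress genes held no member past the threshold out of 13 in edgeR's test, with Edem1 (0.23 ± 0.08), Manf (0.35 ± 0.12) and Chac1 (0.27 ± 0.11) the nearest (list adjusted p = 0.24, 0 when adjusted over the list alone). Among 11 lysosome and autophagy genes the cholesterol transporter gene Npc1 rose (0.33 ± 0.09; 0 when adjusted over the list alone, list adjusted p = 0.27), and Hexb (0.39 ± 0.15) and Ctsb (0.45 ± 0.27) were not past the threshold. Npc1 lost its call without any 1 library other than coculture replicate 2 (adjusted p from 0.0517 to 0.105). Among 11 antioxidant genes the glutathione synthesis gene Gclc rose (0.32 ± 0.08; 1 when adjusted over the list alone, list adjusted p = 0.66), and Gsr (0.28 ± 0.09) and Keap1 (-0.23 ± 0.07) were not past the threshold. Gclc lost its call without alone replicate 2 (0.0737), alone replicate 3 (0.0637) or coculture replicate 3 (0.0613). Of the RNA editing enzymes, the cytidine deaminase genes Apobec3 (0.70 ± 0.14) and Apobec1 (0.42 ± 0.09) rose and Rbm47, a cofactor of the second, fell (-0.44 ± 0.11), with a list adjusted p of 0.40 and the same 3 calls when adjusted over the list alone; Rbm47 lost its call without alone replicate 2 (0.0784), alone replicate 3 (0.0711) or coculture replicate 1 (0.0679). Markers of other cell types were measured in 1 gene each: Cd14 of immune cells (1.58 ± 0.16) and Elf3 of epithelial cells (1.09 ± 0.19) rose, and Des of muscle (-0.48 ± 0.08) fell, each also when adjusted over the list alone. In all, 6 of 17 tested lists were past the threshold, and none with an estimated correlation (1 at an unadjusted p under 0.05, and 11 with fry, which asks only whether the members move 1 way).

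**Figure D3:**
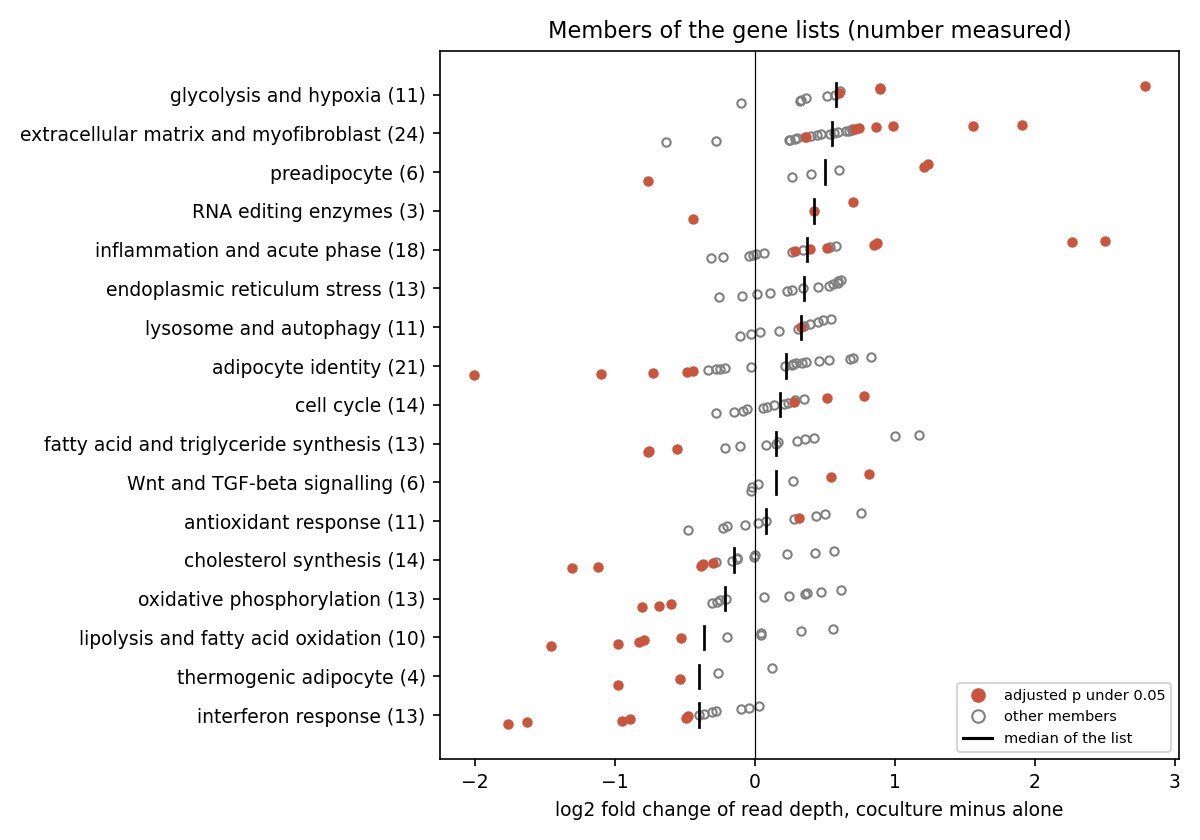
Log2 fold change of read depth, coculture minus alone (horizontal axis), of each measured member of the 17 tested gene lists (rows, with the number measured). Filled points are past the threshold and the bar is the list median, which runs from -0.40 for the interferon response to 0.58 for glycolysis and hypoxia.

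A-to-G substitutions, the form in which A-to-I RNA editing is read, made up 17.57, 17.65 and 17.63% of substitutions on a known strand in alone and 17.63, 17.49 and 17.71% in coculture, where the Wilson intervals of single libraries span 17.30 to 17.86%. The group means differed by -0.004 percentage points (exact permutation test, two-sided p = 0.9), or by 0.07 points at a depth of at least 20 (p = 0.1, the smallest possible). Among 3004 A-to-G positions read at least 10 times in every library with an intermediate fraction, the mean alternate fraction was 50.01 ± 0.10% in alone and 50.06 ± 0.33% in coculture (SD, n = 3 each; exact permutation p = 1.0). Of the other classes, measured in the same way, C-to-T positions had 49.7 ± 0.20% and 49.8 ± 0.29%, and T-to-C positions 50.3 ± 0.11% and 50.3 ± 0.37%. Of the 3004 A-to-G positions, 143 were known to lack a dbSNP identifier. Most of the others are listed there and could be genomic variants, as could most calls behind the A-to-G share. Neither value can therefore show that editing was unchanged. At positions without a dbSNP identifier the fraction was higher in coculture by 1.043 points for A-to-G (44.0 ± 0.53% in alone, 45.1 ± 0.15% in coculture; exact permutation p = 0.1) and by 0.82 points for C-to-T (exact permutation p = 0.1). Over all classes, the differences at such positions ran from -0.56 for G-to-T (exact permutation p = 0.6) to 1.85 for T-to-G (exact permutation p = 0.2).

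Among A-to-G sites of the genes named in advance, Copa I164V was past the threshold, and Blcap Q5R and Y2C were called only in coculture. In Copa, a coat protein gene of vesicle transport, the I164V site (mm10 chromosome 1, 172092348, coding exon 6) carried the edited base in 62.8 ± 2.5% of reads in alone and 51.6 ± 1.2% in coculture (SD, n = 3 each; 391 to 483 reads in alone, 195 to 475 in coculture). Its adjusted p was 0.0496, and the call ended without any 1 of the 6 libraries (0.0864 to 0.508), with a depth minimum of 5 (0.0692), with the replicate block (0.12) and in the quasi-binomial model (0.884). The log2 odds ratio was -0.64, and -0.58 to -0.74 without 1 library, and the call held at a depth minimum of 20 (0.0336). Genes of both strands cover this Copa position, so A-to-G is its change on the genome strand and the transcribed strand is not certain. In Blcap, a small gene expressed in many tissues, the coding sites Q5R (chromosome 2, 157558140) and Y2C (157558149, both coding exon 2) were called in all 3 coculture libraries and in none cultured alone. The edited base made up 10.5 ± 1.2% of reads at Q5R and 19.1 ± 5.0% at Y2C in coculture, on 198 to 416 reads. Read depth of Blcap itself was lower in coculture (-0.83 ± 0.14, adjusted p = 0.00369). The other tested A-to-G sites of the genes named in advance were close between the groups, none past the threshold. Copa N984S was at 61.9 ± 1.7% in alone and 60.5 ± 1.8% in coculture, and Cog3 I635V at 92.7 ± 2.7% and 93.6 ± 1.1%. Igfbp7 K95R was at 39.0 ± 2.7% and 42.6 ± 3.5%, and Igfbp7 R78G at 43.3 ± 0.8% and 44.5 ± 0.4%. Copa N984S and both Igfbp7 sites are listed in dbSNP and could be genomic variants. The Igfbp7 sites also lie in a segmental duplication. The filamin sites Flna Q2333R and Flnb Q2296R were called in 3 and 4 libraries, at 10.7 to 16.2%. No edited coding position of Cyfip2 or Azin1 was called in at least 3 libraries.

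**Figure D4:**
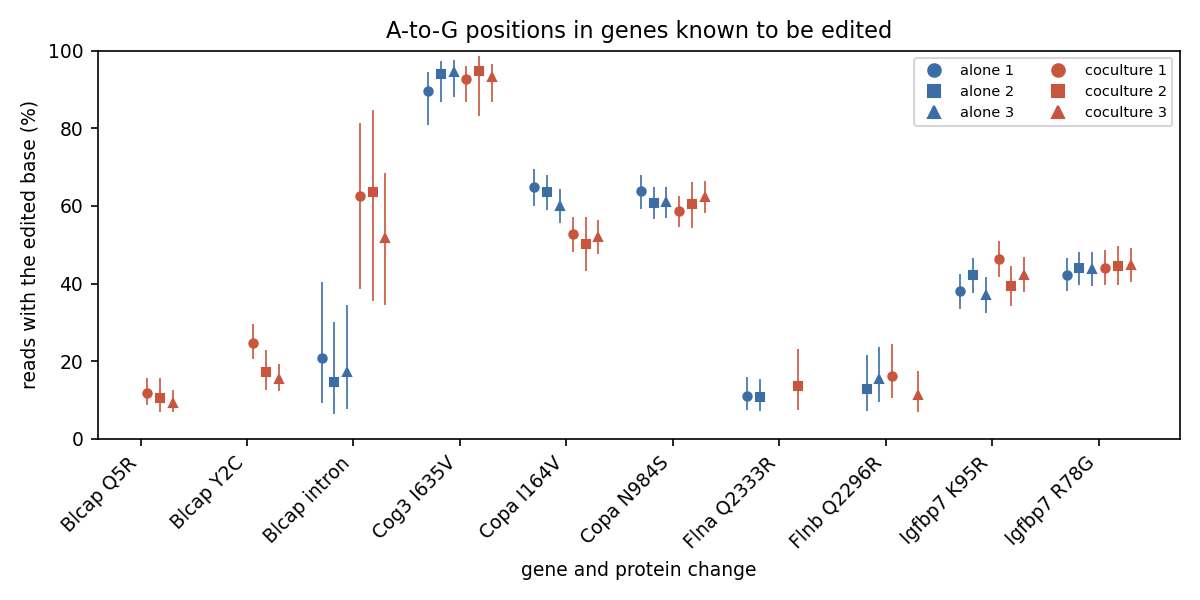
Percent of reads with the edited base (vertical axis) at A-to-G positions of genes known to be edited, per library where called, with 95% Wilson intervals. Blcap Q5R and Y2C have points in the 3 coculture libraries only, the intronic Blcap position rises from 17.6 to 59.3%, and Copa I164V falls from 62.8 to 51.6%.

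The allele fraction was tested at 27312 positions, each called in all 6 libraries. Of these, 25 in 14 genes were past the threshold in edgeR's test, 16 with more of the alternate base in coculture and 9 with less. Positions were not spaced here, so neighbours covered by the same reads count separately among the 25. At an unadjusted p under 0.05 there were 1309. The smallest p-values belonged to synonymous positions in Cwc22, Itih4 and H2-Q4. In the splicing factor gene Cwc22, R851R (chromosome 2, 77896181, coding exon 21) had 87.0 ± 2.5% alternate reads in alone, but 82.2, 48.9 and 47.0% in the coculture libraries, and R877R (77896103) had 81.2 ± 4.2% in alone and 80.6, 31.9 and 37.1%. Without coculture replicate 3 the log2 odds ratio of R877R went from -1.50 to -0.75 and its call ended (adjusted p = 0.9). At both positions coculture replicate 1 was thus like alone. In the major histocompatibility gene H2-Q4, Y94Y (chromosome 17, 35380037, coding exon 2) rose from 32.9 ± 4.9% to 53.3 ± 3.4% and P92P (35380031) from 37.9 ± 4.3% to 57.2 ± 2.9%. H2-Q4 lies in a segmental duplication, so reads of related genes can enter both values. Itih4 F82F (chromosome 14, 30887960, coding exon 2) differed only in alone replicate 1, with 46.2% of 52 reads against 100% of 526 to 685 reads in every other library. The count of 25 dropped to 12 without alone replicate 1, 14 without alone replicate 3 and 13 without coculture replicate 3. A quasi-binomial model called 0 positions (1314 at an unadjusted p under 0.05).

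Calls confined to a group were mostly shallow. There were 8735 substitution positions called in all libraries cultured alone and in no coculture library, and 1289 the other way round, with median depths of 4 and 3 reads. Because coculture replicate 2 is shallow, each count compares with other sets of 3 libraries: 3427 to 6081 positions in the other sets without that library, and 584 to 1093 in the other sets with it. At a depth of at least 20 there were 130 and 19, against 25 to 40 and 4 to 16 in those other sets. Coding changes confined to alone numbered 49 (up to 43 in other sets) and those confined to coculture 18 (up to 10 in other sets with coculture replicate 2), or 11 and 5 at a depth of at least 20. The genes with most such changes in alone were H2-T23 and Pcdhga12 with 4 each, Obox6 with 3, and H2-K1, Klra7 and Rsad2 among those with 2. Those of Pcdhga12, Obox6, H2-K1, Klra7 and Rsad2 were read at most 5 times, while H2-T23 M304T was read up to 80 times. All H2-T23 changes lie in a segmental duplication, so reads of related genes can enter them. Blcap, Mcub and Tmem132b were among those with 2 in coculture, where Mcub was read at most 13 times and Tmem132b at most 6 times.

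Genotypes mostly agreed between libraries where both had a call. A position called in only 1 library of a pair was not compared, so this agreement alone does not show a single cell line. At positions shared by a pair of libraries, 93.7 to 95.0% of genotypes were the same, and 98.9 to 99.1% at a depth of at least 20. Pairs within a group shared 94.6% and pairs between groups 94.5% (exact permutation test of the group labels, one-sided p = 0.1, the smallest of 10 regroupings), a difference of 0.112 points that was 0.01 at a depth of at least 20 (one-sided permutation p = 0.3). The Jaccard index of called positions ran from 0.377 to 0.517.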

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

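The tests of lower Blcap depth, of other edited sites, of segmental duplications and of uneven depth were chosen after their results had been seen, as were both measurements of data outside the per-gene depth. The tests of human RNA and of other splits were not.

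Signal appeared in 2 kinds of calls that the comparison of annotated genes does not use. Measured from their exons, 4 of 58 X-linked genes were higher and 6 lower in coculture. The ETS factor gene Elf4 rose (log2 fold change 1.15 ± 0.11, SE) and so did Apln, which encodes the peptide apelin (0.60 ± 0.11), while Dock11 (-1.64 ± 0.16), Zfp185 (-1.43 ± 0.17) and the sterol synthesis gene Nsdhl (-0.26 ± 0.08) fell. Outside annotated genes, 156 of 1290 tested windows of 10000 bases were higher and 180 lower. Of these, 46 and 89 have measured positions that span no GENCODE gene. On mm10, the window over the end of Ctcflos (chromosome 2, 173130000 to 173139999), measured past that end on the side of Pck1, had -2.15 ± 0.12, beside Ctcflos, Ctcfl and Pck1, which all fell. Positions between Gstp3 and Cabp2 (window on chromosome 19, 4060000 to 4069999) had 2.19 ± 0.14.

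The 8 inflammation genes that rose could owe their change to the depth ceiling with its shallow library. At positions of mean depth up to 150 and without coculture replicate 2, the 5 members still measured had a median log2 fold change of 1.08 (0.69 to 2.50). This speaks against it for these 5. RNA of the human Panc-1 cells would add bases that the adipocytes lack. The mouse reference base was counted at 37 positions, homozygous in alone, in 6 of these genes. It was carried by 0.058% of 13801 coculture reads and 0.020% of 10051 alone reads, far below the 5% set in advance. The deposited counts hold only reads with the reference or the alternate base. At such positions over all genes, 0 of 6410195 coculture reads carried any other base, so reads with other bases were evidently not counted. The ceiling is thus excluded as the whole cause for those 5 members only. For the members not measured at such positions it was not tested and stays open. Human RNA with the mouse reference base at these positions is excluded as the whole cause for these 6. Human RNA with the adipocytes' own base there, or with a base that was not counted, stays open, because the counts cannot show it. An effect of the coculture remains a hypothesis.

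The 6 interferon genes that fell were put to similar tests. Their median was -0.87 below the depth ceiling without coculture replicate 2. Of the 6, 0 have a measured position in a segmental duplication, so reads shared between the copies of such duplications are excluded. Reads shared with less similar relatives, as within the Gbp family, were not tested and stay open beside an effect of the coculture.

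Blcap carried A-to-G calls at 2 coding sites in coculture only, and its intronic position on chromosome 2 (157558645), seen after the fact, went from 17.6 ± 3.1% to 59.3 ± 6.6% of reads (adjusted p = 0.015; 24 to 34 reads in alone, 11 to 29 in coculture). Fewer Blcap reads in alone could hide such calls, but the log2 fold change of Blcap depth was -0.83, so alone had more. A general rise of editing stays open: of the other 5 edited sites, the pair in Igfbp7 and Copa N984S are listed in dbSNP, as is Blcap Y2C itself, and could be genomic variants, and Copa I164V and Cog3 I635V alone (median log2 odds ratio -0.28) are too few to exclude it. A fraction in alone just under what the caller reports, or a shift between Blcap transcripts, stays open, because positions without a call carry no read counts.

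The 6 libraries can be split into 3 and 3 in only 10 ways, the real split included, too few for a share under 0.05. The real split gave 1625 genes and the highest other 0 in edgeR's test (174 at an unadjusted p under 0.05), so 1 of the 10 splits gave as many. It gave 25 allele-fraction positions against 13 at most elsewhere, again 1 of the 10. For gene lists 4 of the 10 splits gave at least the real count of 6, and the split of alone 1, alone 2 and coculture 2 from the rest gave 8. Below a mean depth of 150 the real split gave 8 lists and that same split 6, the highest other.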

How the results depend on the processing

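Positions of mean depth up to 150, their 2 combinations, added X-linked genes and passing calls were chosen after seeing the data; the other alternatives were planned. Of the 66 measured genes named by the rule, 828 of 873 values under the alternatives and 362 of 396 with a library left out kept direction and side of the threshold. The called genes among these 66 kept their direction. Over all genes, between 452 and 814 higher or lower genes were called in the same direction under each setting, and 1 gene was called in the opposite direction, with depth 0 at uncalled positions. Mcm3, Ppargc1b, Npc1, Gclc, Rbm47, Dgat1 and P4ha2 lost their call most often. Elf3 (adjusted p = 0.23), Cox5b (0.0577) and Cd44 (0.0667) lost it with depth 0 at uncalled positions, and Apobec3 (0.137) and Idi1 (0.691) with 1 position per gene. Ctsb turned to 0 without coculture replicate 2, -0.04 up to a mean depth of 150 and -0.05 there with the replicate block, and Col1a1 to -0.12 up to 150 without coculture replicate 2. The cause was not tested beyond the depth ceiling.

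Genes higher numbered 531 with 1 position per gene and 502 at homozygous positions, and 501 were lower at homozygous positions, where fewer genes were tested (3973). With a library left out, higher genes ran from 500 to 1066, lower genes from 455 to 1100, lists past the threshold from 4 to 7, allele-fraction positions from 12 to 24 and the difference in calls from -96889 to -18187. Lists numbered 0 with an estimated correlation (1 unadjusted) and 11 with fry. The antioxidant list (0.42 without coculture replicate 1) turned to a lower direction without coculture replicate 2 (adjusted p = 0.95), up to a mean depth of 150 (0.73) and there without that library (0.64). Allele-fraction positions numbered 0 in the quasi-binomial model (1314 unadjusted). Cog3 I635V turned to a log2 odds ratio of -0.25 without alone replicate 1 (0.3 without alone replicate 3), and without that library Itih4 F82F gives no value.

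The A-to-G share differed by 0.07 percentage points at a depth of at least 20 (exact p = 0.1), 0.452 without dbSNP identifiers (p = 0.4), 0.019 in passing calls (p = 0.8) and -0.055 to 0.057 with a library left out; without alone replicate 2 it was 0.012, without alone replicate 3 0.006. The A-to-G fraction differed by 1.043 points without dbSNP identifiers (exact p = 0.1), 0.473 at a depth of at least 5 and -0.138 to 0.146 with a library left out. A design of 3 against 3 says nothing of the stability of these p-values. Group-restricted positions fell to 130 (alone) and 19 (coculture) at a depth of at least 20, with 11 and 5 coding changes. Leaving out a library loosens the rule, giving 10198 to 20380 and 2290 to 9049 positions, and 67 to 126 and 24 to 83 coding changes.

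Same-numbered libraries did not deviate together in every pair (r across genes -0.183, -0.053 and 0.167). Up to a mean depth of 150 these were -0.051, -0.012 and 0.141. Only replicate 3 correlated best with its own number. So few pairs cannot settle whether the numbers pair the libraries. With the replicate block 650 genes were higher, 626 lower, 6 lists and 19 allele-fraction positions past the threshold, and the A-to-G share differed by -0.004 points. Up to a mean depth of 150 it gave 845 and 823 genes. Depth limits what could be seen: 1.5-fold changes were recovered in 51% of simulated genes.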

Other observations

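The lists and genes below were put together after the values had been seen, so their tests describe these libraries and are not independent evidence.

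Immediate early transcription factor genes were higher in coculture in 9 of 12 measured members (camera adjusted p = 3.1e-07, and adjusted p = 0.023 with an estimated correlation). Junb rose 4.01-fold (log2 fold change 2.00 ± 0.10, SE), Ier3 3.57-fold (1.84 ± 0.11) and Klf4, a Krüppel-like factor gene, by 1.09 ± 0.09. Receptors of interleukins and tumour necrosis factor were higher in 8 of 13 (adjusted p = 0.0011, and adjusted p = 0.047 with an estimated correlation), among them Il17ra (1.31 ± 0.19), Il4ra (0.96 ± 0.12) and Tnfrsf1b (0.92 ± 0.09). Il1r1 and Il6st, also among the 8, are inflammation genes that rose as well, so these lists are not separate. The acute phase genes Lbp (2.46 ± 0.28) and Fgl1 (2.55 ± 0.28), which the liver secretes, also rose, on mean depths of 21.3 and 18.8 reads. Cytosolic aminoacyl-tRNA synthetase genes were higher in 6 of 16 (adjusted p = 0.0024, adjusted p = 0.047 with an estimated correlation, and 0.10 up to a mean depth of 150), with Cars (0.77 ± 0.10) and Wars (0.47 ± 0.08).

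Class I antigen presentation genes were lower in 9 of 20 measured members (adjusted p = 0.0024, and adjusted p = 0.10 with an estimated correlation). Of these, Psmb9, Psmb8 and Tap1 are also among the interferon genes that fell, so the lists are not separate. Nlrc5, the activator of class I genes, fell 2.07-fold (-1.05 ± 0.14), and Tapbpl (-0.96 ± 0.08) and Erap1 (-0.43 ± 0.13), which shape the peptide load, fell too. The falls of H2-T22 (-1.01 ± 0.17), H2-Q1 (-0.65 ± 0.08) and H2-Q4 (-0.42 ± 0.08) are uncertain, since these genes share reads with near-identical copies, and H2-K1 (0.52 ± 0.25) and B2m (0.49 ± 0.30) were not past the threshold. Branched-chain amino acid breakdown genes were lower in 6 of 13, among them Mccc2 (-0.77 ± 0.12) and Pccb (-0.49 ± 0.08), with a list adjusted p of 0.079 (0.33 with an estimated correlation).

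Further A-to-G positions with a changed fraction lay outside the genes named in advance. In Adhfe1 an intronic position (chromosome 1, 9550215) went from 69.1 ± 1.7% to 85.9 ± 4.9% of reads (SD, n = 3; edgeR adjusted p = 0.00994), and in the 3' UTR of Rpa1 (chromosome 11, 75301015) the fraction went from 97.7 ± 1.1% to 87.7 ± 3.3% (adjusted p = 0.0056). Retsat held 4 of the 25 changed positions, none of them A-to-G, with V84I (chromosome 6, 72601053, coding exon 2) at 48.5 to 65.5% in alone and 65.6 to 71.3% in coculture. Its neighbours A83A (72601052) and A82A (72601049) had nearly the same read counts, so they are not separate results. Trem2 A118V, confined to coculture and read up to 69 times, stood beside a rise of Trem2 depth (1.40 ± 0.11). Across genes, the first principal component of depth at positions up to a mean of 150 held 60.9% of the variance and separated the groups, and the second (17.6%) set coculture replicate 2 apart from the other coculture libraries.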
